A study of Drosophila melanogaster with 3 samples.

How the data were processed

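Chromatin was sonicated to a size range of 200 to 800 bp per the labels, and DNA bound to GFP-tagged GAGA factor was recovered from whole embryos in 3 biological replicates. The labels number the replicates 1, 2 and 3, and these numbers are used throughout. The authors deposited a peak list for each replicate, a pooled list made from all 3, and an optimal list thresholded by IDR (irreproducible discovery rate), each on dm6 and dm3. Per the deposited text notes, the replicate and pooled lists hold peaks and background as input for IDR. The caller, the aligner and their versions are not given in the sources used here. The signal value and the −log10 q-value of each peak are the authors' deposited values, and the summit is the authors' deposited offset from the peak start. The signal scale is not stated, so signal was used only for rank within a list. The −log10 q-value ran from 3.49 to 3.97 in the optimal list and was not used further. The depth of the replicates is unknown, because peak lists give no read totals, and signal tracks and the control IP were not used here.

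The dm6 lists were the main ones. The optimal list was identical to the top 4900 of the 30000 pooled peaks by signal, and 5 of its intervals are repeated with another summit. All dm6 peaks lay on 2L, 2R, 3L, 3R, X and 4 and ended within the reference lengths of these 6 arms. The dm3 lists (4625 optimal peaks) served as an alternative, with no coordinates moved between builds. Genes and start sites came from Ensembl release 115 (dm6 coordinates), without transposable elements, which left 13945 protein-coding genes.

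Peaks overlapped when they shared at least 1 bp, and replicates were compared over the top 4900 peaks of each list. A percentile is the rank of a peak in a replicate list of 30000, and a gene without a peak in a replicate was given 0 there. Promoter peaks had a summit within 500 bp of a start site. Chance was measured by 1000 circular shifts along each arm (two-sided permutation test). Motifs were sought on both strands within 100 bp of the summit and in windows centred 1000 bp to either side and outside optimal peaks, with Fisher's exact test. A gene was bound when an optimal summit lay within 500 bp of any of its start sites. Lists were tested by Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over 28 lists and a threshold of 0.05, and against 10000 random lists matched on start sites and gene length in 5 classes. Exact 95% binomial (Clopper-Pearson) intervals cover counting error only. Peaks and neighbouring genes are not independent, so p-values over them are too small, and the values of each replicate's own top 4900 give the biological spread. The share found in all 3 lists is an exception, since its 3 values count nearly the same overlaps and differ little by construction. Motif and promoter shares are read from the same reference at mostly shared peaks, so their spread is also small in part by construction. Percentiles of optimal peaks are high, with a small spread, in part for a like reason, since these peaks were called from the same replicates. The 2 arm comparisons were adjusted together under each alternative too. With 1 group, no comparison between conditions was made.

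The gene lists, motifs, the tests of each comparison and most alternatives were fixed before the data were examined, with these exceptions. Fisher's exact tests between deciles, the promoter strata and the motif counts per gene list were added after the shares had been seen. A total of 4 listed symbols that did not match the annotation were matched by hand afterwards (Delta, nanos, lolal and caly). The symbol pattern of the innexin and ion channel list also caught unrelated genes and was narrowed after its first result had been seen. Both were run again as first written, and the counts of lists past the threshold stayed at 4 and 6. Some members have another role than the name of their list says, such as Rab3GAP1 among Rab genes and Ptx1 and hbn in the pair-rule list. Genes were named by a rule: Trl, the 10 strongest peaks with their nearest protein-coding start site, and in each list up to 4 bound members by signal and up to 2 unbound members in alphabetical order, fewer where the text would become a catalogue. The genes nearest to a named peak, such as Gpdh1, CenG1A and CG7943, were named after their values were seen.

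The alternatives were other overlap rules (reciprocal 0.5, summits within 100 bp), promoter windows of 100 and 1000 bp, motif windows of 50 and 250 bp, flanks at 500 bp, the stronger 2450 optimal peaks, other start site sets, the top peaks of each replicate alone, each replicate left out, and dm3. The code was tested on simulated data. A simulated promoter share of 48.1% among 4900 peaks was measured as 48.1%, and all 500 planted GAGAG windows were recovered. Both outcomes follow nearly by construction. The expected share was computed with the same code, and GAGAG was planted inside the window searched. They therefore show only that the code runs without gross errors. For gene lists over 13945 genes, simulated lists bound at 60% against 23% of other genes were recovered in 96 of 100 runs with 40 members, 63 of 100 with 20 members and 40 of 100 with 12 members, and 7 of 2700 unchanged lists were called. A short list that is not past the threshold is therefore not shown to be like other genes. Overlap counts equalled those of bedtools 2.31.1. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.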

Results

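GAGA factor, the product of Trithorax-like (Trl), is a zinc finger protein that binds GA-rich DNA. Its positions on chromatin were measured by ChIP-seq in whole Drosophila melanogaster embryos of mixed sex, collected from 0 to 24 h of development. The embryos carried Trl with an inserted GFP exon, and the tagged protein was recovered with an antibody against GFP. The data form 1 group of 3 biological replicates with no second condition, so the comparisons are between replicates and between peaks and features of the genome. The authors' thresholded set, called the optimal peaks here, held 4900 peaks on dm6, and each replicate had a relaxed list of 30000 peaks that includes background calls. The peak lists give no read totals, so the depth of each replicate is unknown. Peak signal is the authors' own value and was used only to rank peaks within a list.

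The first comparison asked how far the 3 replicates marked the same places. The strongest optimal peaks lay beside Ugalt, which encodes a UDP-galactose transporter, cbt, which encodes a zinc finger transcription factor, and CG14100. These were followed by peaks beside Lk6, a protein kinase gene, CG11050, Chro, which encodes the chromosomal protein Chromator, and CG1888. The remaining peaks of the 10 strongest lay beside ph-p, which encodes a Polycomb group protein, Art3, an arginine methyltransferase gene, and PNPase. All 10 ranked between 1 and 11 in each replicate list. The Ugalt peak covered X from 2703684 to 2704092 on dm6, with its summit 32 bp upstream of the start site, and ranked 2, 2 and 1 in replicates 1, 2 and 3. The cbt peak covered 2L from 480854 to 481301, in an intron annotation 1366 bp upstream of the nearest protein-coding start site of cbt. The CG14100 peak covered 3L from 19590416 to 19590821 in intergenic sequence 96 bp upstream of its start site. The Chro peak covered 3L from 22878695 to 22879096 in a 5' UTR, and the ph-p peak covered X from 2137148 to 2137560 in an intron annotation, 480 bp upstream of the ph-p start site.

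Among the top 4900 peaks of each replicate list, a mean of 68.1% overlapped a top 4900 peak of both other replicates. The 3 lists gave between 67.98% and 68.22%, but they count nearly the same three-way overlaps, so this closeness is no measure of the biological spread. Pairs of replicates shared 77.3% (1 and 2), 77.6% (1 and 3) and 77.3% (2 and 3). Circular shifts of the peaks of replicate 1 gave a mean of 1.93% and at most 2.90% over 1000 shifts. The share fell with depth, from 81.0% among the top 100 peaks to 50.4% among the top 20000. Of the optimal peaks, 4883 of 4900 (99.7%, exact 95% binomial interval 99.4 to 99.8) overlapped a peak in all 3 full replicate lists, against a mean of 6.03% for shifted positions. Across 4883 peaks, which are not independent replicates, Spearman's rho of the signal was 0.741, 0.737 and 0.747 for the 3 pairs. The optimal peaks were called from the same replicates, so their overlap is not an independent check.

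**Figure D1:**
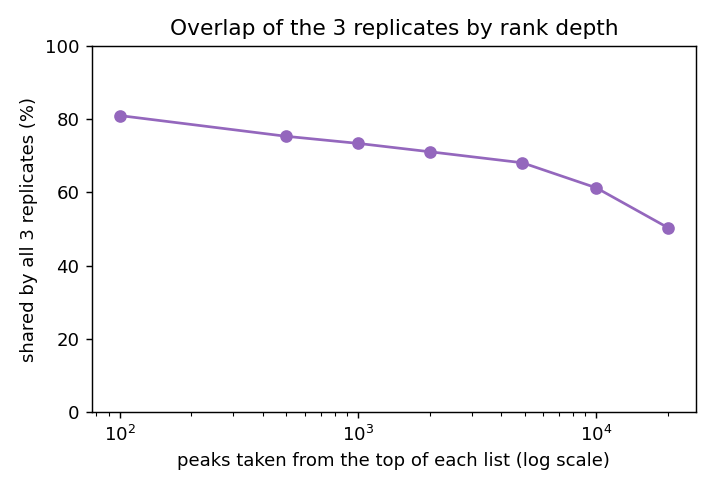
The share of peaks found in the top of all 3 replicate lists is plotted against the number of peaks taken from each list, on a log axis. Points are means over the 3 lists, and the share falls from 81.0% at 100 peaks to 50.4% at 20000.

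The second comparison placed the peaks relative to genes. Trl itself (FBgn0013263, minus strand of 3L from 14747929 to 14761049, dm6) had 6 optimal peaks within the gene or 2 kb around it. The strongest of these covered 14759303 to 14759715 in an intron, had a signal of 831.4 and stood at rank 56 of 4900. In the replicate lists it lay at the 99.8 ± 0.0287 percentile (SD, n = 3). The second covered 14757049 to 14757458 in a 5' UTR, 82 bp from a Trl start site, and lay at the 98.2 ± 0.332 percentile (SD, n = 3). Of the 6 peaks, the one at 14762221 to 14762630 lay outside the gene, and the nearest start site, 398 bp away, was that of Mgat4a. GAGAG was present within 100 bp of the summit in the peaks at 14755146 to 14755555, 14758004 to 14758413 and 14760095 to 14760504, and in none of the others.

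**Figure D2:**
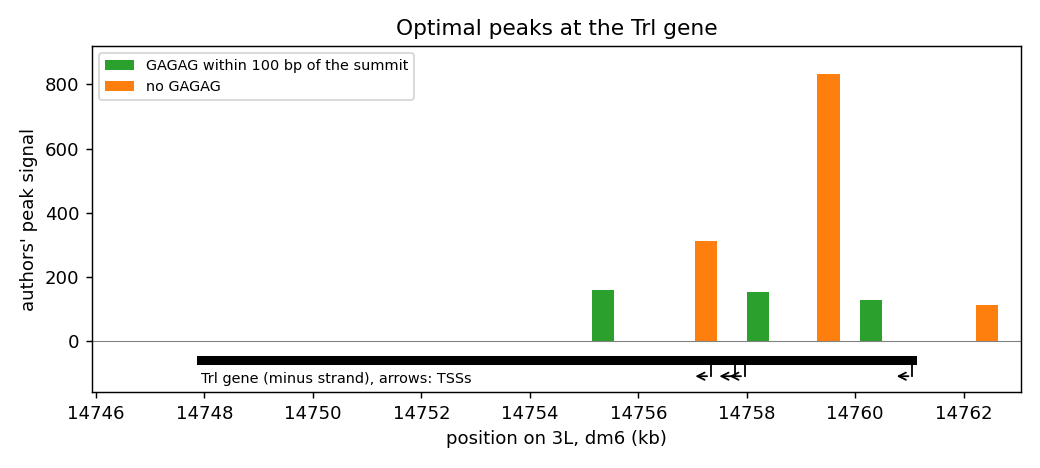
Optimal peaks at Trl are drawn to scale along 3L (dm6, kb), with bar height showing the authors' peak signal in their own units and colour showing whether GAGAG lies within 100 bp of the summit. The black bar is the gene, arrows mark its annotated start sites, and the peak with a signal of 831.4 lies in an intron. The peak at 14762221 to 14762630 lies outside the gene, nearest to a start site of Mgat4a.

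Start sites held 56.8% of optimal summits within 500 bp (2785 of 4900, exact 95% binomial interval 55.4 to 58.2). Shifted positions gave a mean of 13.6% and at most 15.6%, a ratio of 4.18 (two-sided permutation p = 0.001, the smallest that 1000 shifts can give). The top 4900 peaks of the replicates gave 56.7% ± 0.821 (SD, n = 3). Introns held 42.8% of optimal summits, intergenic sequence 39.0%, 5' UTRs 13.1%, 3' UTRs 1.35% and coding exons 0.694%. These classes include promoter summits. Intronic summits over 500 bp from a start site were 29.7% of all optimal summits, and intergenic ones 10.9%. In pooled peaks below the authors' threshold, coding exons held 18.9% and promoters 28.1% (7063 of 25100). The median distance from an optimal summit to a start site was 292.5 bp, and 586 summits lay over 5 kb away.

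The third comparison asked which sequences lay under the summits. GAGAG, the core of the known GAGA factor site, stood within 100 bp of 1596 of 4900 optimal summits (32.6%, exact 95% binomial interval 31.3 to 33.9). It was present in 22.6% of flanking windows centred 1000 bp away (Fisher's exact p = 3.68e-37, adjusted p = 1.01e-36 over the motifs tested). The longer repeat GAGAGAG was found in 11.2% of peaks and 3.58% of flanks, a ratio of 3.14. The DRE, TATCGATA, bound by the transcription factor DREF, was present in 4.55% of peaks and 0.611% of flanks, a ratio of 7.45 (Fisher's exact p = 2.91e-55). Flanks were not matched for distance to a start site, and the DRE was not compared in peaks away from promoters. Its ratio therefore cannot separate these peaks from promoters in general. AGGAG and GGAGA, which hold the bases of GAGAG in another order, were less frequent in peaks than in flanks, at 14.0% against 28.9% and 22.2% against 27.6%. The Zelda site CAGGTAG was present in 1.10% of peaks and 1.18% of flanks (Fisher's exact p = 0.741). Among all strand-merged 5-mers, GAGAG (written CTCTC on the other strand) ranked 6 by the ratio of peaks to flanks, and CACTG ranked 1 with a ratio of 1.60. In the top 4900 peaks of the replicates GAGAG was present in 32.7% ± 0.747 (SD, n = 3).

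The strongest decile of peaks held GAGAG less often and promoters more often, both at the windows used here. In the strongest decile GAGAG was present at 130 of 490 summits (26.5%, exact 95% interval 22.7 to 30.7), and in the other deciles at 1466 of 4410 (33.2%; Fisher's exact p = 0.00269). Flanks of the strongest decile held GAGAG at 23.3% (exact 95% interval 20.6 to 26.2). This interval overlaps that of its summits, so an excess over flanks was not clear in the strongest decile. Flanks of the other deciles held it at 22.5%. The replicates gave 27.4% ± 0.425 in the strongest decile of their own top 4900 and 33.3% ± 0.853 in the rest (SD, n = 3). Fisher's exact p for this difference was 0.00278, 0.0409 and 0.00398 in replicates 1, 2 and 3. The replicate lists share most of their peaks, so this spread is small in part by construction and does not test the difference. The shares did not rise steadily (30.4% in decile 2, 28.6% in decile 3, 37.6% in decile 8 and 31.6% in decile 10), and within 250 bp of the summit the direction turned, with GAGAG at 58.4% in the strongest decile and 55.9% in the others. Among the 10 strongest peaks, the one beside Lk6 held GAGAG and the other 9 did not. Within promoter peaks, GAGAG stood at 22.0% of summits in the strongest decile and 34.9% in the others, while away from promoters the values were 35.3% and 31.1% (Fisher's exact p = 0.26). Promoters held 65.9% of summits in the strongest decile and 51.2% in the weakest (Fisher's exact p = 3.97e-06). With a promoter window of 100 bp the strongest decile was 3.27 percentage points below the weakest and no longer past the threshold (Fisher's exact p = 0.287).

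**Figure D3:**
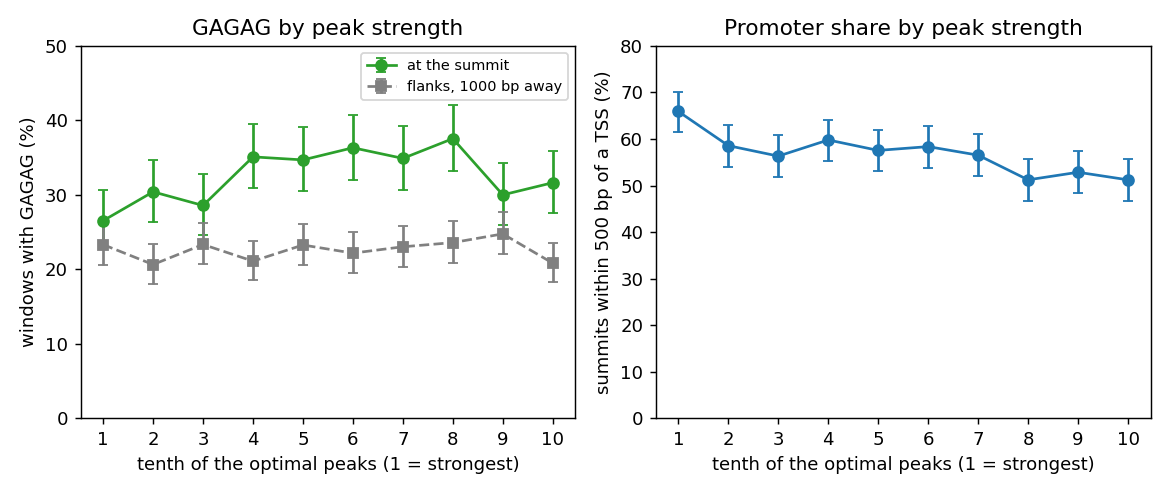
Both panels run from the strongest (1) to the weakest (10) decile of the 4900 optimal peaks, with exact 95% binomial intervals. The left panel gives the percent of windows with GAGAG at summits and in flanks, lowest at summits in decile 1 (26.5%), and the right panel the percent of summits within 500 bp of a start site, highest in decile 1 (65.9%).

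The fourth comparison asked which of 28 gene lists had bound promoters, meaning an optimal summit within 500 bp of a start site. Ribosomal protein genes were bound at 69 of 92 promoters (75.0%, exact 95% interval 64.9 to 83.4) and mitochondrial ribosomal protein genes at 34 of 73 (46.6%). Trithorax group genes, which maintain active gene states, were bound at 13 of 19 promoters, and Polycomb group genes, which maintain repressed states, at 11 of 20. Over all protein-coding genes 3193 of 13945 promoters (22.9%) were bound, and 22.6% ± 0.0908 (SD, n = 3) in the replicates' top 4900. No odorant receptor (59), gustatory receptor (60) or cuticle protein (117) promoter was bound.

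Each of the 4 lists bound more often passed Fisher's exact test (two-sided) after Benjamini-Hochberg adjustment over the 28 lists. The adjusted p was 9.25e-25 for ribosomal protein genes, 3.89e-05 for mitochondrial ribosomal protein genes, 0.000122 for trithorax group genes and 0.00521 for Polycomb group genes, with odds ratios of 10.3, 2.96, 7.32 and 4.13 by Fisher's exact test. The top 4900 peaks of each replicate bound 74.3% ± 3.32, 43.4% ± 1.58, 64.9% ± 3.04 and 53.3% ± 7.64 of these lists (SD, n = 3). The trithorax group odds ratio was 3.50 with 1 start site per gene (Fisher's exact adjusted p = 0.0218), and matched lists gave a mean of 7.10 of 19 bound (adjusted p = 0.0312, random list permutation, the highest over its 12 alternatives). The Polycomb group result was not past the threshold in replicate 2 alone (Fisher's exact adjusted p = 0.0605) or against 10000 random lists matched on gene length and number of start sites (adjusted p = 0.0987, random list permutation), the highest over its 12 alternatives. With a window of 100 bp, the mitochondrial ribosomal protein result was not past it (Fisher's exact adjusted p = 0.72, the highest over its 12 alternatives).

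RpS27 and RpL7, which encode cytosolic ribosomal proteins, had promoter peaks at ranks 48 and 54 of 4900, at the 99.8 ± 0.0386 and 99.8 ± 0.0437 percentiles of the replicate lists (SD, n = 3). RpL23A and RpL32 followed at ranks 74 and 86, the latter nearest to the start site of CG7943, and RpL10 and RpL10Aa were unbound. The mRpS10 and mRpS23 peaks stood at ranks 9 and 11, but the nearest protein-coding start sites to their summits were those of Art3 and CenG1A. Ribosomal protein peaks lay at a median percentile of 97.3 ± 0.341 in the replicates, against 92.9 ± 0.0441 for all bound genes (SD, n = 3). Ranked within the optimal peaks only, the median percentiles were 83.5 and 57.9. Among Polycomb group genes, ph-p, Psc, Sfmbt and Su(z)2 had the strongest peaks, at ranks 8, 242, 893 and 1293, and Asx and Caf1-55 were unbound. The Psc peak covered 2R from 12980788 to 12981039 (dm6) in a 5' UTR and held GAGAG. Among trithorax group genes, Trl, lola, brm and lolal had peaks at ranks 514, 688, 764 and 778, and Bap111 and Set1 were unbound. The brm peak covered 3L from 15982892 to 15983086 in intergenic sequence, 77 bp upstream of the start site of this gene for the ATPase of the Brahma remodelling complex.

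The 6 lists bound less often by the same test were those of odorant receptors (Fisher's exact adjusted p = 2.14e-06), gustatory receptors (1.63e-06), cuticle proteins (1.01e-12), Jonah and trypsin proteases (0.00521), seminal fluid proteins (0.000535) and replication histones (4.55e-12). The odds ratio was 0.0729 for seminal fluid proteins and 0 for the others by Fisher's exact test, and the top 4900 peaks of each of the 3 replicates gave the same counts. The exact 95% upper limits on the share bound were 6.06% for odorant receptors, 5.96% for gustatory receptors, 3.10% for cuticle proteins and 12.8% for the proteases. Of 27 protease promoters none was bound, and of 47 seminal fluid protein promoters 1 was, that of Sfp26Ad, whose peak lay nearest to the start site of Gpdh1. Or10a, Gr10a, Ccp84Aa, Jon25Bi and Acp1 are examples without a promoter peak. None of 111 histone genes was bound, but these are near-identical copies to which short reads map poorly, so the count is uncertain. The protease and seminal fluid results were not past the threshold against matched lists (adjusted p = 0.351 and 0.256, random list permutation, the highest over 12 alternatives each), nor in the stronger 2450 peaks (Fisher's exact adjusted p = 0.0967 and 0.0697), nor for the proteases at 100 bp (0.168).

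The other 18 lists were not past the threshold after adjustment, although 4 of them passed it under some alternatives and most had 22 members or fewer, a size at which simulated differences were often missed. Heat shock genes were bound at 4 of 17 promoters (Fisher's exact adjusted p = 1), with Hsp83, Hsp27 and Hsp26 at the 99.4 ± 0.241, 99.1 ± 0.184 and 98.9 ± 0.338 percentiles (SD, n = 3) and Hsp22 the fourth. The Hsp26 peak covered 3L from 9377294 to 9377703 (dm6), 72 bp upstream of its start site, with GAGAG. CG4456 and DnaJ-1 of this list were unbound, and members with near-identical copies are uncertain. Chromatin and insulator genes were bound at 9 of 21 promoters (Fisher's exact adjusted p = 0.0879), led by Chro, Dref and Cp190. Ecdysone response genes were bound at 6 of 14 (Fisher's exact adjusted p = 0.225), led by E23, Eip75B, usp and ftz-f1. The ecdysone response result passed the threshold in the top 4900 of replicates 1 and 3 (Fisher's exact adjusted p = 0.00319 and 0.0027), and over its alternatives the adjusted p ran from 0.000486 to 1. The chromatin and insulator result passed it in the top 4900 of replicate 2 (Fisher's exact adjusted p = 0.0375) and in the stronger 2450 peaks (0.0140), with a highest value of 0.37 against matched lists. The Rab result passed it in the top 4900 of replicate 2 (Fisher's exact adjusted p = 0.0375), at 100 bp (0.0190) and with gene bodies (0.0337), and was at 1 in the stronger 2450 peaks. The innexin and ion channel result passed it with gene bodies (Fisher's exact adjusted p = 0.0144) and was at 1 in the stronger 2450 peaks.

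In the embryonic patterning lists the share of bound promoters was not past the threshold in either direction. These lists are too short to decide whether promoters were bound less often, and the simulated differences were all toward more binding. With the top peaks of replicate 3 alone, no Hox promoter was bound and the Fisher's exact adjusted p was still 0.335. With 1 start site per gene, no promoter of the hemocyte and fat body list was bound (Fisher's exact adjusted p = 0.192). Hox genes were bound at 1 of 8 promoters, that of Abd-B, whose peak lay at the 71.0 ± 28.3 percentile (SD, n = 3), with Antp and Dfd unbound. The Hox odds ratio was 0.481 at promoters and 2.53 with gene bodies and 1 kb upstream (Fisher's exact adjusted p = 0.939 and 0.365). Gap and maternal genes were bound at 3 of 12 (bcd, btd and ems), the pair-rule list at 2 of 12 (the homeobox genes Ptx1 and hbn), segment polarity genes at 4 of 12 (ptc, nkd, inv and mid) and dorsoventral genes at 4 of 16 (rho, brk, pyr and dpp). Kr, eve, arm and Doc1 were unbound. Unbound means only that no optimal summit lay within 500 bp of a start site. Peaks elsewhere in the gene or below the authors' threshold are not counted. Notch pathway genes were bound at 5 of 17 promoters, led by gro, neural genes at 5 of 22, led by elav, and muscle genes at 6 of 15, led by sls. Germline genes were bound at 6 of 15, led by bgcn, hemocyte and fat body genes at 1 of 14 (ush), and gut and endoderm genes at 2 of 13 (fkh and pnt). Proteasome genes were bound at 10 of 48, Rab genes at 14 of 36, innexin and ion channel genes at 7 of 21, and dosage compensation genes at 1 of 5 (msl-1).

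**Figure D4:**
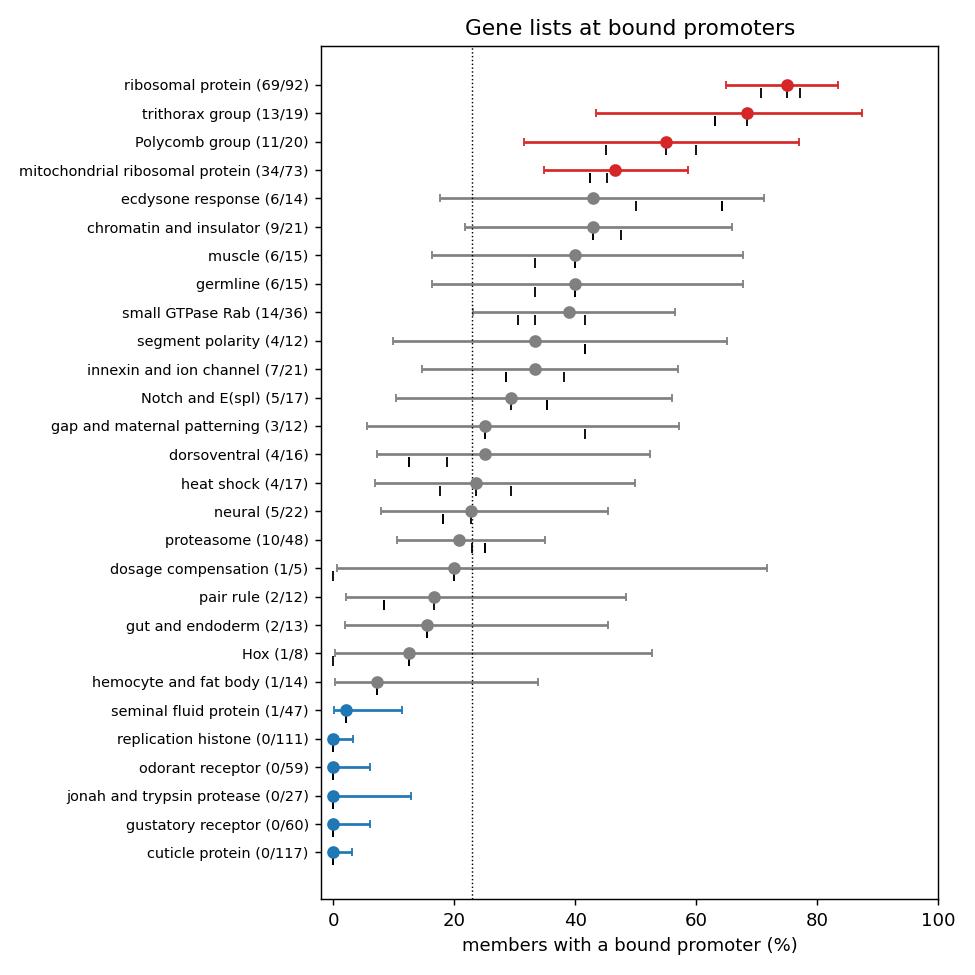
The percent of each list's members with a bound promoter is shown for the optimal peaks (points, with exact 95% binomial intervals) and for the top 4900 peaks of each replicate (black ticks). Red and blue mark lists bound more and less often than other genes after adjustment, grey the rest, and the dotted line the 22.9% of all protein-coding genes; ribosomal protein genes stand highest at 75.0%.

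The fifth comparison set the chromosome arms side by side, since dosage differs between X and the autosomes and chromosome 4 is rich in heterochromatin. Chromosome 4 had bound promoters at 7 of 80 protein-coding genes (8.75%, exact 95% interval 3.59 to 17.2), against 23.2% on the other autosomes (odds ratio 0.318, Fisher's exact p = 0.00125, adjusted p = 0.0025 over the 2 arm comparisons). It held 11.1 optimal peaks per Mb and 14.3 ± 1.87 (SD, n = 3) of the replicates' top 4900, while the other arms held between 33.8 (3L) and 39.6 (2L) optimal peaks per Mb. X had bound promoters at 482 of 2196 genes (21.9%), against 23.1% on autosomes (odds ratio 0.938, Fisher's exact p = 0.257, adjusted p = 0.257). The difference for X was past the threshold in the stronger 2450 optimal peaks (odds ratio 0.759, Fisher's exact p = 0.000168, adjusted p = 0.000335) and with a promoter window of 100 bp (odds ratio 0.8004, Fisher's exact p = 0.00421, adjusted p = 0.00842). The difference for chromosome 4 was not past the threshold in 2 of the 3 replicates. With the top 4900 peaks of each replicate alone its odds ratio was 0.321 in replicate 1 (Fisher's exact p = 0.00184, adjusted p = 0.00369), 0.481 in replicate 2 (p = 0.0314, adjusted p = 0.0628) and 0.542 in replicate 3 (p = 0.0602, adjusted p = 0.120, the highest over its 6 alternatives).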

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

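The tests of base composition, promoter share and the DRE in the strongest decile, the Fisher test between deciles and the Breslow-Day test were chosen after the results they bear on had been seen in whole or in part. The first results given here come from peaks outside the optimal list and from the dm3 lists.

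In pooled peaks below the authors' threshold, GAGAG stood within 100 bp of 7069 of 25100 summits (28.2%, exact 95% interval 27.6 to 28.7), against 22.1% of their flanks (Fisher's exact p = 8.31e-74). The share was uneven, at 33.1% against 22.5% of flanks for ranks 4901 to 10000 and 25.2% against 21.6% for ranks 25001 to 30000. Shoulders of optimal peaks are argued against, since the 22234 summits with no optimal summit within 1000 bp kept an excess of 5.75 percentage points (95% bootstrap interval 5.06 to 6.45). Base composition alone is argued against too, since the log2 ratio of GAGAG exceeded that of AGGAG and GGAGA by 0.24 (95% bootstrap interval 0.20 to 0.29). GAGAG was 5.54 percentage points more frequent in peaks found in all 3 replicate lists than in the rest (95% bootstrap interval 4.41 to 6.67), which is consistent with weaker binding below the threshold, a hypothesis, and no biological difference between samples was available to test it.

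On dm3, 28 pooled peaks lay on scaffolds outside the 6 arms, and the replicate lists held 35, 58 and 74 for replicates 1, 2 and 3. None was in the optimal list, and the highest pooled signal there was 63.4, against a lowest optimal signal of 89.5.

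GAGAG was less frequent in the strongest decile than in the others. A mere excess of promoters there is argued against, since with the GAGAG shares of the other deciles the promoter share of the strongest would give a difference of 0.386 percentage points (95% bootstrap interval 0.0920 to 0.767) where -6.71 was observed (-11.1 to -2.56), and Fisher's exact odds ratios of 0.525 in promoter peaks and 1.21 in other peaks differed by a Breslow-Day test (p = 0.000128). Base composition stays open, since AGGAG and GGAGA fell as well. Their mean log2 ratio, strongest decile to others, was -0.55 (95% bootstrap interval -0.86 to -0.27). The log2 ratio of GAGAG was higher than this by 0.22 (95% bootstrap interval -0.08 to 0.58), so GAGAG was not shown to fall more than they did. The share of A and T bases at summits was 61.7%, 62.5% and 62.1% in the strongest decile of replicates 1, 2 and 3. In their other deciles it was 59.7%, 60.4% and 59.9%. Summits displaced from the motif stay open too, since within 250 bp the difference was 2.45 percentage points (95% bootstrap interval -2.27 to 6.85). Sites of another factor were the only biological explanation tested, and only the DRE was examined. It was present in 3.27% of the strongest decile and 4.69% of the others. The difference was -1.43 percentage points (95% bootstrap interval -3.06 to 0.34), so its sign is not settled. An excess of at most 0.34 points is far too small for the GAGAG difference of -6.71. This argues against DRE sites as the whole cause, and sites of other factors stay open.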

How the results depend on the processing

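The rows for 250 bp windows, peaks below the threshold as the comparison, lists without histone genes, lists as first written, lists without hand-matched symbols, and rank agreement and percentiles without each replicate were chosen after seeing the data. Of 509 alternatives, 434 kept direction and side of the threshold, stayed within the replicate spread or the binomial interval or, for counts of lists, stayed within 1.5 times the main count. Of these 434, 285 were rows of single gene lists, which also feed the counts of lists. Some rows could hardly change, such as those of lists whose members the symbol changes did not touch. The count is therefore no measure of robustness. Promoter and GAGAG shares were past the threshold under every alternative run. The share of optimal peaks in all replicate lists was 86.0% by reciprocal overlap, 90.2% by summits, 99.96% for the stronger 2450 peaks and 95.3% in the top 10000, and 99.7% to 99.8% without each replicate. The top 4900 shared 60.7% by reciprocal overlap and 58.5% by summits, the top 1000 shared 73.4% and the dm3 lists 68.5%. Without each replicate the share was 77.3% to 77.6%, since sharing by fewer lists is easier by construction. Mean rho was 0.771 in the stronger 2450 peaks and 0.737 to 0.747 without each replicate. The strongest decile minus the others for GAGAG was 2.45 points with deciles made among peaks away from promoters, and strongest minus weakest for promoters was -3.27 points at 100 bp. The 4 lists bound more often became 7 with gene bodies and 1 kb upstream, 5 at 1000 bp, in the stronger peaks and in each replicate, and 3 against matched lists. The 6 bound less often became 5 at 100 bp and without histone genes, and 4 in the stronger peaks and against matched lists. The odds ratio for X was 0.8004 at 100 bp and 0.759 in the stronger peaks, and that for chromosome 4 was 0.481 in replicate 2 and 0.542 in replicate 3. At 1000 bp the median percentile of bound genes was 93.1, and without each replicate 92.9 to 92.95. Lists not past the threshold changed side of 1 (odds ratio, or ratio to matched lists) as follows. Hox was 2.53 with gene bodies. Gap genes were 0 at 100 bp, 0.95 at 1000 bp, 0.605 in the stronger peaks and 0.915 matched. Segment polarity was 0.711 at 100 bp. Dorsoventral was 0.95 at 1000 bp, 0 in the stronger peaks, 0.896 with 1 start site per gene, 0.785, 0.488 and 0.491 in replicates 1, 2 and 3, and 0.885 matched. Heat shock was 0.488 at 100 bp, 0.832 with 1 start site and 0.729 in replicate 1. Ecdysone response was 0.601 at 100 bp, 0.299 with 1 start site and 0.982 matched. Neural was 1.005 in replicate 2, and muscle 0.558 at 100 bp and 0.978 matched. Gut was 1.21 in the stronger peaks. Proteasome was 1.57 at 100 bp, 1.14 in the stronger peaks, 1.13, 1.02 and 1.15 in replicates 1, 2 and 3, and 1.11 matched. Rab genes were 0.831 and ion channels 0.700 in the stronger peaks, and ion channels 0.898 matched. Where no construction is named, the cause was not tested. Read depth is unknown, so what it limits could not be measured.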

Other observations

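The GAGAG counts per gene list in the next paragraph were added after the data had been seen, and the lists named were chosen from them.

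GAGAG stood within 100 bp of the summit in 33.4% of all promoter peaks, and the counts per gene list given here are small and were not tested against it. GAGAG was present in 4 of 4 promoter peaks of the segment polarity list, 3 of 3 of the gap list and 1 of 1 of the Hox list. The pair-rule list had 2 of 2, at Ptx1 and hbn, which have another role than the name of the list says. The dorsoventral list had 2 of 4, where rho and brk held GAGAG and pyr and dpp did not. The ptc peak on 2R from 8649339 to 8649748 (dm6), the bcd peak on 3R from 6759589 to 6759784 and the Abd-B peak on 3R from 16934187 to 16934596 are examples with GAGAG. In the ecdysone response list 5 of 6 peaks held GAGAG, in the germline list 0 of 6, and in the mitochondrial ribosomal protein list 5 of 34. The heat shock list had 2 of 4, the muscle list 3 of 6, the Polycomb group list 3 of 11 and the trithorax group list 3 of 13. The gene of the noncoding RNA roX1, which acts in dosage compensation, had a peak at its promoter, and roX2 did not.

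Ribosomal protein gene promoters were bound more often than others. Short genes with few start sites are argued against as the whole cause, since 69 were bound and the highest count in 10000 matched lists was 38. Peaks of neighbouring genes are argued against for most members, since 91.3% of the bound members (63 of 69) had their own start site nearest to the summit (exact 95% interval 82.0 to 96.7). Being bound required a summit within 500 bp of the gene's own start site, which favours this outcome. No share for other bound genes is given for comparison. More frequent GAGAG near the summits of these peaks is argued against as well, since the odds ratio was 0.255 against other promoter peaks (8 of 69 peaks, 11.6% against 34.0%, Fisher's exact p = 4.36e-05). Promoters without a peak and windows wider than 100 bp were not compared, so GAGAG elsewhere in these promoters stays open. Promoters open in most cells remain a possible explanation, a hypothesis that was not tested because expression and a control IP were not used here.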
